A study of Escherichia coli with 18 samples.

How the data were processed

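The data are RNA-seq libraries of Escherichia coli K-12. Per the labels, cultures A, B and C grew for 48 h in sterilised lake water. The medium held phosphate at 1 mM and yeast extract at 100 mg/L, at a pH of about 8.4. Each was exposed to 400 µM ferrate, 35 µM hypochlorite or water, and samples were taken before and after 15 min, so each combination of culture and exposure is treated as a flask with a library before and a library after. Cells were washed and kept in RNAlater. RNA was extracted with a column kit, treated with DNase and depleted of rRNA, and libraries were made with a stranded kit.

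The deposited table holds read counts per gene, raw and not normalised, with a column for each of the 18 libraries. The values are whole numbers that differ between all libraries. Per the submitters' processing notes, FastQC, BWA, featureCounts and Subread were used with genome build ASM584v2; their versions and settings are not given in the sources used here. The strand setting is not stated, so counts of genes that overlap on opposite strands are uncertain, and how reads from repeats were counted is not stated either. The table has 4497 genes, of which 99 have 0 counts in all 18 libraries, and 0 columns were left unused. Locus tags gave the gene names. Of them 4487 matched the reference annotation and 10 did not, and 348 genes took their name from the reference alone. Coordinates are on ASM584v2.

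Total counts per library ran from 11055260 to 25561297. Replicate libraries differ by far more than counting error, so the precision of a comparison is set by the spread between flasks, and errors given with log2 changes are standard errors from the model.

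Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by filterByExpr with its default settings, library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion and a mean for each of the 6 groups was fitted to the 18 libraries. This left 4385 genes. The comparisons were after against before for each exposure, each disinfectant against water after exposure, the difference between the changes of each pair of exposures, and each disinfectant against water before exposure. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 32 gene lists were written from background knowledge before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and fry beside it. Counts of list genes that passed are also given adjusted over the list alone. DESeq2 1.42.0 was the other tool.

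The genes named in the text follow a rule set before the data were examined. For the comparisons of changes over time and of these changes with each other, it takes the 8 highest and 8 lowest log2 changes. These must pass the test, have a mean CPM of at least 10 and the same sign in all 3 cultures, and structural RNA and insertion sequence genes are left out. It adds the 2 members with the smallest adjusted p from each list called, and 8 sentinel genes in every comparison (katG, ahpC, soxS, rclA, ibpA, fecA, recA and cysK). For the other comparisons it takes 3 and 3 genes and the sentinels. The text gives all sentinels for after against before, their range for the comparisons after exposure, and only part of them elsewhere. Genes named outside this rule are said to be chosen after their values were seen.

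The culture letters pair the libraries. The pairing was checked by correlating residuals of the fit. The mean correlation was -0.0130 over 45 pairs of libraries of the same culture, 0.00789 over 90 pairs of different cultures and -0.109 over the 9 pairs from the same flask, so the fit without a block was used and fits with culture or flask as a block were run as alternatives. Blocked values stand beside a result where they change a call or move a count by over 1.5 times.

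The spread of reads over genes was measured as follows, a measure chosen after seeing the data. Of 3690 protein-coding genes of at least 300 bp and 180 counts in all, the 923 in the lowest 25% before exposure were taken as quiet genes. Their median count per kb in a library is its flat level. The flat share is this level times the length of all protein-coding genes, as a percentage of the protein-coding counts. In the model of dilution, also chosen after seeing the data, the library after exposure is predicted for each flask from its library before, multiplied by a scale, plus the flat level. The scale is the median over expressed genes, so departures are relative to that median. Genes count as clear where they depart by at least 1 on the log2 scale, pass at an adjusted p of 0.05 and stand at 3 or more times the flat level in all 3 libraries, as observed for higher genes and as predicted for lower genes.

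The alternatives set beforehand were DESeq2, RLE size factors in edgeR, no filter and a stricter filter on low counts (a CPM of 10 in 3 libraries), culture or flask as a block, structural RNA left out, a fit of only the groups compared, and leaving out each library in turn. Those added after seeing the data were leaving out the after libraries of cultures A and C of water and hypochlorite together, in which the flat share is over 50%, while hypochlorite culture B at 55.6% was kept so that the group holds a library. The others were leaving out single libraries in the list tests, and the model of dilution. Where an alternative leaves 1 library in a group, that library is assumed to vary like those of the other groups. Calls kept or gained in such a fit rest on 1 library of that group and do not show that a result holds.

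The steps were tested on simulated data. Runs for edgeR changed 100 genes 2-fold and 100 genes 4-fold, with all libraries drawn from the mean profile before exposure. With the spread between replicates taken from all libraries, edgeR recovered 44% of genes changed 2-fold and 86% of genes changed 4-fold in the ferrate comparison, with 6 false calls among 4366 genes. For the ferrate change against the hypochlorite change it recovered 13 and 69%, with 9 false calls. With the spread taken from the libraries before exposure alone, recovery was 68 and 97% for ferrate and 34 and 94% for the ferrate change against the hypochlorite change, with 8 false calls in each. These runs gave a gene the same spread in every group and no flat share that differs between replicates. Their false calls thus give no error rate for the data. When only a flat component was added to the libraries before exposure, edgeR called 2188, 3357 and 1950 genes for ferrate, hypochlorite and water, and the model of dilution called 0, 0 and 0 clear genes. With 200 genes raised 4-fold as well, the model recovered 187 of 191 in ferrate, 27 of 56 in hypochlorite and 0 of 53 in water among raised genes over 3 times the flat level. Both runs were drawn from the equation of the model itself, with the spread of the libraries before exposure alone. The 0 clear genes were thus close to fixed and give no error rate for the data, where libraries after exposure vary more. The water flasks themselves gave 22 clear genes. Figures were drawn with matplotlib 3.10.9.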

Results

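The series set potassium ferrate, an iron salt used as an oxidising disinfectant, against sodium hypochlorite, the active agent of bleach, and asked how the transcripts of Escherichia coli K-12 responded to each. Cultures A, B and C were each split over a water control, 400 µM ferrate and 35 µM hypochlorite, and RNA was taken before and after 15 min. This gave 6 groups of 3 RNA-seq libraries, 18 in all. The total count per library ran from 11055260 to 25561297. The group means were 17.2 M counts for water before, 18.7 M for ferrate before and 15.6 M for hypochlorite before. After exposure they were 22.8, 22.2 and 11.6 M in the same order.

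The libraries differed in how their reads were spread over the genes, and this moved with exposure. Before exposure most protein-coding counts came from strongly expressed genes. Between 1615 and 2517 genes per library stood at 3 or more times the flat level, the reads per kilobase typical of genes that were quiet before exposure. A component spread over all genes in proportion to their length, at that level, made up 6.21% ± 2.32 (SD, n = 9) of the protein-coding counts. After exposure it made up 32.9% ± 1.58 (SD, n = 3) in ferrate, with 31.6, 32.4 and 34.6% in cultures A, B and C. In hypochlorite it was 73.6% ± 15.8 (SD, n = 3), with 80.6, 55.6 and 84.7%, and in water 51.0% ± 39.2 (SD, n = 3), with 87.8, 9.89 and 55.4%. Each increase had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, and an adjusted p of 0.15 over 6 comparisons. Ferrate after differed from water after by -18.2 percentage points (exact permutation p = 0.6, adjusted 0.6) and from hypochlorite after by -40.8 (exact permutation p = 0.1, adjusted 0.15). Genes at 3 or more times the flat level numbered 600, 597 and 562 in ferrate after, 64, 298 and 40 in hypochlorite after, and 24, 1723 and 321 in water after. The tmRNA gene ssrA, whose product rescues stalled ribosomes, took 6.85 to 30.6% of all counts in the libraries taken before. It took 40.1 to 47.8% in ferrate after, 2.10 to 18.7% in hypochlorite after and 0.793 to 32.3% in water after.

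**Figure D1:**
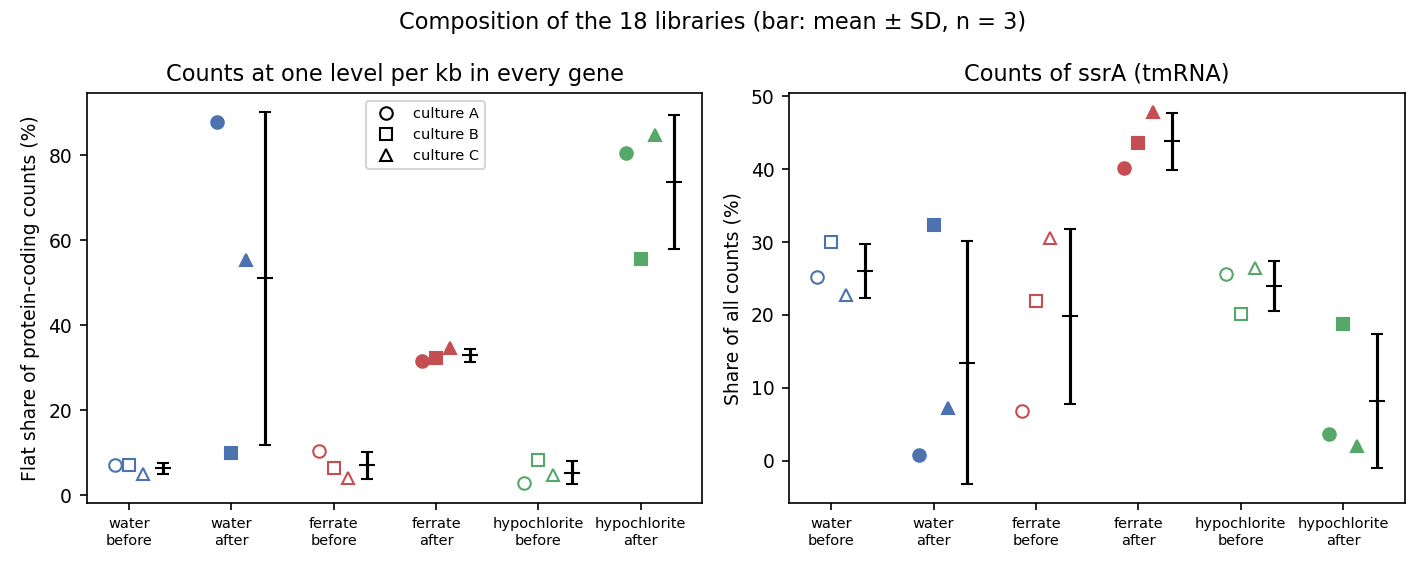
Share of the protein-coding counts in the flat, length-proportional component (left, percent) and share of all counts from ssrA (right, percent) in each of the 18 libraries, with symbols for the cultures and bars for the mean ± SD (n = 3). After exposure the flat share lies between 31.6 and 34.6% in ferrate and between 55.6 and 84.7% in hypochlorite, while the water libraries run from 9.89 to 87.8%.

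The first comparison asked what changed in the ferrate flasks over the exposure. grxA and trxC, of the glutathione and thioredoxin systems that reduce protein disulfides, led the rises. grxA, the gene of glutaredoxin 1 (b0849, positions 890496 to 890753 on ASM584v2), rose by 3.46 ± 0.34 on the log2 scale (SE from the fit of all 6 groups, n = 3 flasks, adjusted p = 5.99e-05). trxC, the gene of thioredoxin 2 (b2582, positions 2718735 to 2719154), rose by 3.09 ± 0.61 (adjusted p = 0.00281). Both belong to the OxyR peroxide regulon and both were higher in 3 of 3 cultures. trxC stood at 31.0 times the flat level before and at 85.4 times after, and grxA at 1.12 and 4.17 times. katG, the catalase-peroxidase of the same regulon, rose by 0.66 ± 0.18 (adjusted p = 0.00681), a call that RLE size factors end (0.41, adjusted p = 0.0766). Relative to the flat level katG went down in 3 of 3 cultures, from a mean of 6.17 to 3.05 times.

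The other 6 genes with the largest rises after ferrate were yhaK, yqaE, wbbJ, pinE, yijF and yghS, which rose by 2.42 to 2.70. yqaE stood at 6.22 times the flat level after exposure and yhaK at 2.26 times, while the other 4 lay between 0.952 and 1.67 times. The largest fall was of asnA, an asparagine synthetase (b3744, positions 3927155 to 3928147), which fell by 4.25 ± 0.65 (SE, adjusted p = 0.00111) and went from 107 to 1.67 times the flat level. fabG of fatty acid synthesis fell by 3.89, aceA, the isocitrate lyase, by 3.83 and rho, the termination factor, by 3.57. yobF and its neighbour cspC, a protein of the cold shock family, changed by -3.76 and -3.54, and bsmA and ymgA by -3.85 and -3.61. The adjusted p of these 7 genes ran from 0.000373 to 0.00729. All 16 genes changed in the same direction in 3 of 3 cultures.

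Among the sentinel genes chosen beforehand, rclA of the reactive chlorine response fell by 0.62 ± 0.17 (SE, adjusted p = 0.00723) and cysK, cysteine synthase A, by 1.37 ± 0.38 (adjusted p = 0.0078). The changes of the remaining 5 did not pass the test. They were -0.72 for ahpC of the alkyl hydroperoxide reductase (adjusted p = 0.0832), -1.11 for soxS, the superoxide response activator (0.107), 0.56 for the small chaperone ibpA (0.0648), 0.03 for the ferric citrate receptor fecA (0.913) and -0.31 for recA (0.372). ahpC passed as lower under DESeq2, RLE size factors and a fit of the ferrate libraries alone (adjusted p from 0.00332 to 0.0351), soxS under the first and last (0.0286 and 0.0021) and recA under the last (0.0261). fecA turned negative under DESeq2 and RLE (-0.20 in each).

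Of the 32 gene lists fixed beforehand, 7 were lower after ferrate in the camera test, and none of these calls holds with an estimated correlation. Of 54 ribosomal protein genes 17 were lower and 0 higher (median -0.88, camera adjusted p = 8.04e-05, and adjusted p = 0.818 with an estimated correlation), with rpsK and rpsT (-0.74) the members with the smallest p. Of 21 histidine and branched-chain amino acid genes 12 were lower and 3 higher (median -0.77, adjusted p = 0.00238, and adjusted p = 0.591 with an estimated correlation), with hisI at -3.31 and hisG at -1.80. For the next 5 lists the adjusted p was 0.818 with an estimated correlation. Arginine biosynthesis had 8 of 11 genes lower and 0 higher (median -0.92, adjusted p = 0.00238), with argB at -2.05 and argH at -1.11. The TCA cycle and glyoxylate shunt had 7 of 17 lower and 0 higher (-0.73, adjusted p = 0.00263), with aceB at -2.82 beside aceA. The RpoS general stress list had 7 of 21 lower and 0 higher (-1.23, adjusted p = 0.00275), with otsA, which makes trehalose phosphate, at -2.76 and the stationary-phase catalase katE at -1.23. NADH dehydrogenase I and the cytochrome oxidases had 13 of 23 lower and 3 higher (-0.62, adjusted p = 0.00392), with nuoC at -1.61 and nuoL at -1.45. The SoxRS list had 10 of 19 lower and 2 higher (-0.64, adjusted p = 0.0217), with ribA at -1.77 and pqiA at -1.61. Adjusted over the list alone, 8 ribosomal, 5 TCA cycle and 6 RpoS genes were lower and 1 arginine gene was higher, and the other counts were the same.

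The other oxidative stress and metal lists did not pass camera after ferrate. In the OxyR list 6 of 13 genes were higher and 1 lower, also adjusted over the list alone (median 0.49, camera adjusted p = 0.423), and fry, which asks only whether a list's genes move one way, gave 0.00392. In the Fur iron acquisition list 14 of 38 genes were higher and 8 lower (adjusted p = 0.701), and of 16 genes of the hypochlorite and electrophile regulons 6 were higher and 5 lower (0.793). In the SOS list, for DNA damage, 12 of 25 genes were higher and 7 lower (0.834), and in Fe-S cluster assembly 1 of 17 was higher and 6 lower (0.0839). With p adjusted over the list alone, these 4 lists had 14, 7, 12 and 0 genes higher and 8, 5, 7 and 4 lower. The flagella and chemotaxis list had 28 of 49 genes higher and 3 lower (median 0.76, adjusted p = 0.0534).

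In all, 2699 of 4385 genes tested changed after ferrate, 1719 higher and 980 lower. RLE size factors moved the median of all genes by -0.24 (log2) and gave 1404 higher and 1308 lower, so that the higher genes went from 63.7 to 51.8% of those called. Of the 1455 genes called higher with a known length, 94.1% lay within 2-fold of the flat level after exposure, with a median of 1.36 times before and 1.11 after. The genes called lower went from a median of 14.6 to 1.82 times.

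**Figure D2:**
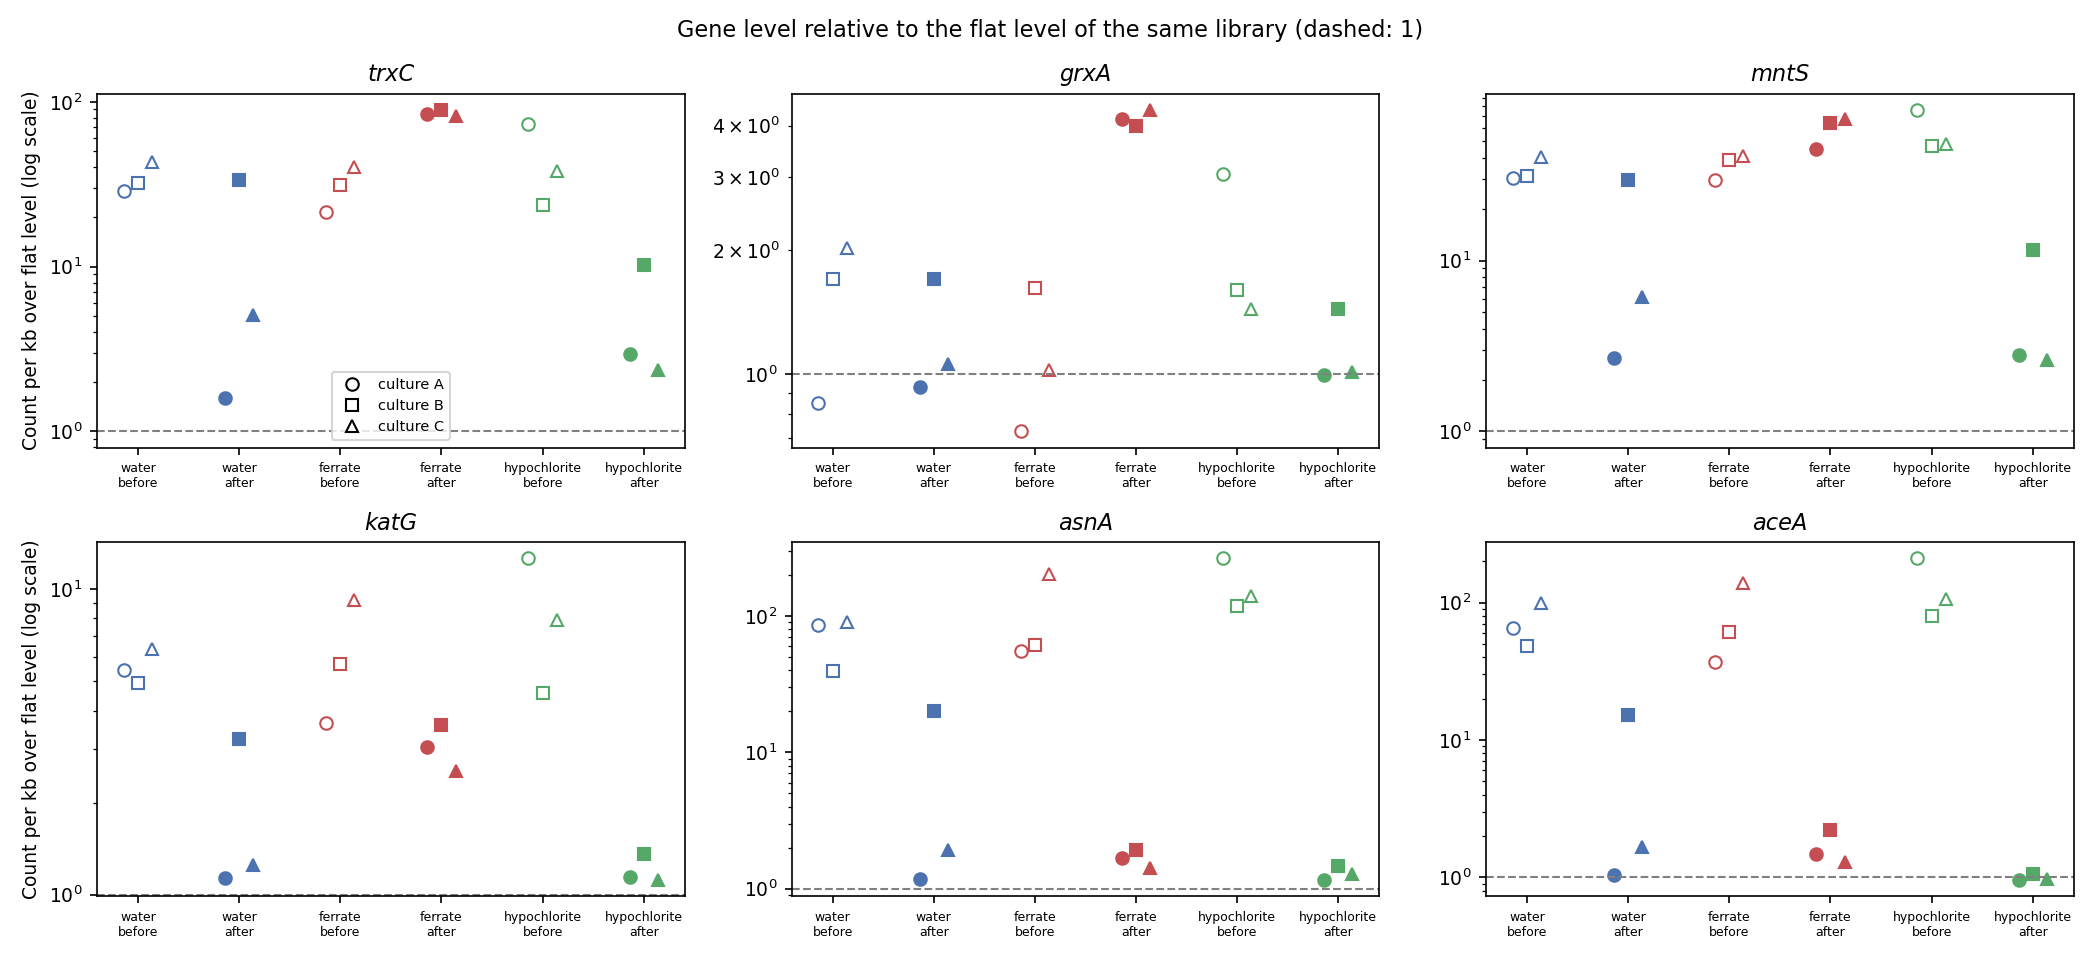
Counts per kb of 6 genes relative to the flat level of the same library (log scale, the dashed line at 1 is the flat level), with each of the 18 libraries as a point by group and culture. trxC has a mean of 85.4 times the flat level in ferrate after, against 13.4 in water after and 5.16 in hypochlorite after.

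The same comparison in the hypochlorite flasks had ycgZ as its largest fall. ycgZ (b1164, positions 1215789 to 1216025) fell by 5.59 ± 1.07 (SE, n = 3 flasks, adjusted p = 0.000348), and ymgA, ariR and ymgC beside it by 5.29, 5.17 and 4.91. csiD, induced on carbon starvation, fell by 5.42 and from 460 to 2.12 times the flat level. nlpD, sra and yjjY fell by 5.04, 4.93 and 4.79, and the adjusted p of these 7 genes ran from 0.000246 to 0.000503. The largest rises were of yfdM (3.88 ± 0.70, adjusted p = 0.00027), yiaM (3.69), eutQ (3.45), yjfL (3.44), ybcN (3.40), sfmH (3.38), cspH (3.37) and yghG (3.36). cspH stood at 3.94 times the flat level after exposure, and the other 7 lay between 0.610 and 1.11 times. All 16 genes changed in the same direction in 3 of 3 cultures.

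Of the sentinels, 5 fell after hypochlorite. soxS fell by 3.56 (adjusted p = 0.000267), cysK by 2.43 (0.000194), ahpC by 1.74 (0.000522), recA by 1.71 (0.000279) and katG by 0.45 (0.0254), a call lost without the after libraries of cultures A and C of water and hypochlorite (-0.45, adjusted p = 0.0963). They ended at 1.20 to 2.34 times the flat level. fecA rose by 0.60 (adjusted p = 0.0386), a call lost with culture as a block (0.59, adjusted p = 0.0547), under DESeq2, under RLE size factors, with structural RNA left out and without the same 4 libraries (0.37, adjusted p = 0.303). rclA was at -0.32 (0.0855, and 0.0027 to 0.03 under DESeq2, RLE and with structural RNA left out) and ibpA at 0.19 (0.486), and ibpA turned to -0.011 under DESeq2 and -0.013 under RLE.

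After hypochlorite 14 lists passed camera, 13 of them lower, and for each the adjusted p was 0.562 with an estimated correlation. Ribosomal proteins had 52 of 54 genes lower and 0 higher (median -2.45, camera adjusted p = 2.24e-10), with rpsO at -3.76 and rplS at -1.90. The RpoS list had 20 of 21 lower (-3.29, adjusted p = 7.87e-06), with elaB at -4.54, and the TCA cycle 14 of 17 (-1.43, 0.000323), with aceA at -4.71 and aceB at -3.43. Fe-S cluster assembly had 14 of 17 lower (-2.63, 0.000895), with iscR, its regulator, at -3.70 and iscA at -3.12. Thiol redox and methionine sulfoxide repair had 11 of 15 lower and 1 higher (-1.82, 0.00308), with msrB at -2.30 and msrA at -1.65, and RpoH heat shock had 16 of 20 lower and 1 higher (-1.41, 0.0028), with hslR at -2.18 and hslV at -2.03. The same held for NADH dehydrogenase and oxidases (17 of 23, 0.00238), arginine (9 of 11, 0.0028), SoxRS (14 of 19, 0.00583), histidine and branched-chain amino acids (13 of 21, 0.00583) and envelope stress (16 of 21, 0.0077). ATP synthase (7 of 9, 0.0154) and toxin-antitoxin modules (11 of 18, 0.0165) followed, with atpF at -3.01 and hicA at -2.89. Of the 14 lists 11 stayed without the after libraries of cultures A and C of water and hypochlorite, and histidine and branched-chain amino acids (adjusted p = 0.0569), ATP synthase (0.203) and toxin-antitoxin modules (0.0616) were lost. That fit leaves 1 hypochlorite library after exposure, so the calls kept in it do not show that the lists hold. Flagella and chemotaxis was the list called higher (35 of 49 higher and 5 lower, median 1.21, adjusted p = 0.00308), with fliE at 3.01 and fliI at 2.86. fliE went from 0.595 to 1.18 times the flat level. Adjusted over the list alone, the TCA cycle had 15 and the toxin-antitoxin list 9 lower genes, and the other counts were the same. The OxyR list (4 of 13 higher, 6 lower, 0.525), the hypochlorite and electrophile regulons (6 of 16 higher, 5 lower, 0.97) and the Fur list (22 of 38 higher, 9 lower, 0.431) did not pass.

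In all, 3681 genes changed after hypochlorite, 2004 higher and 1677 lower. RLE size factors moved the median by -0.20 and gave 1865 higher and 1821 lower. Of 1698 genes called higher with a known length 94.7% lay within 2-fold of the flat level after exposure (median 1.62 times before and 1.10 after). The genes called lower went from 22.9 to 1.32 times.

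The water flasks carried no disinfectant, so their change over the 15 min is the background for both exposures. The glyoxylate shunt gene aceA fell by 2.67 ± 0.55 (SE, n = 3 flasks, adjusted p = 0.00635), aceB by 2.32, asnA by 2.38, hisI by 2.08 and the ribosomal genes rpmF and rpmC by 2.31 and 1.92. cdaR fell by 2.24 and soxS by 2.02. The largest rises were of eutN (2.98 ± 0.63, adjusted p = 0.00635), and of fixB, yjfM, yfdO, lyxK, nikB, nrfC and agaB (2.50 to 2.60). These 8 genes lay at 0.608 to 1.65 times the flat level after exposure. cysK fell by 1.72 (adjusted p = 0.00635), ahpC by 1.18 (0.0141) and recA by 0.90 (0.0231), while katG at -0.27 (0.178), rclA at -0.34 (0.0866), ibpA at 0.10 (0.732) and fecA at 0.10 (0.732) did not pass. DESeq2 called katG (-0.40, adjusted p = 0.0162) and rclA (-0.47, 0.0113) lower, and rclA also passed under RLE and with structural RNA left out (0.0379 and 0.0446). Under DESeq2 and RLE ibpA was at -0.034 and -0.028 and fecA at -0.026 in each.

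In the water flasks 13 lists passed camera, 12 of them lower, with adjusted p = 0.598 with an estimated correlation. Ribosomal proteins had 28 of 54 genes lower (median -1.32, camera adjusted p = 3.55e-11), with rpsT at -0.77, the RpoS list 5 of 21 (-1.23, 7.24e-05), with katE at -1.08, and the TCA cycle 9 of 17 (-0.89, 0.000425). RpoH heat shock had 9 of 20 lower (-0.93, 0.000516), with groL at -0.84 and dnaJ at -0.79, and thiol redox 8 of 15 (0.00162), with grxB at -1.55 and msrA at -1.06. Fe-S cluster assembly had 4 of 17 lower (-1.26, 0.00247), with iscR at -1.56. Arginine (9 of 11, 0.00143), envelope stress (8 of 21, 0.00225), NADH dehydrogenase and oxidases (7 of 23, 0.00316), SoxRS (9 of 19, 0.00485), histidine and branched-chain amino acids (10 of 21, 0.0137) and ATP synthase (4 of 9, 0.0199) were lower too. Flagella and chemotaxis was higher (26 of 49, median 0.64, adjusted p = 0.00803, and adjusted p = 0.625 with an estimated correlation), with fliE at 2.18. The calls of flagella and Fe-S cluster assembly were lost without the after libraries of cultures A and C of water and hypochlorite. That fit leaves 1 water library after exposure, of culture B, which correlated at r = 0.984 with the library before of its own flask. The list calls kept in it thus do not show that the lists hold. Adjusted over the list alone, 26 ribosomal, 10 TCA cycle, 11 thiol redox, 6 NADH dehydrogenase, 2 ATP synthase, 1 RpoS and 0 Fe-S genes were lower, and the other counts of lower genes were the same.

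In all, 2443 genes changed in water, 1676 higher and 767 lower, and RLE size factors moved the median by -0.13. Of 1441 genes called higher with a known length 94.9% lay within 2-fold of the flat level (median 1.33 times before and 1.15 after). The genes called lower went from 14.3 to 3.61 times. The count fell to 0 in a fit of the water libraries alone (1781 at an unadjusted p under 0.05, while DESeq2 over the 18 libraries called 2965) and without the after libraries of cultures A and C of water and hypochlorite (152 at an unadjusted p under 0.05). It was 910 without water after A, 1228 without water after C and 1310 without water before C.

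**Figure D3:**
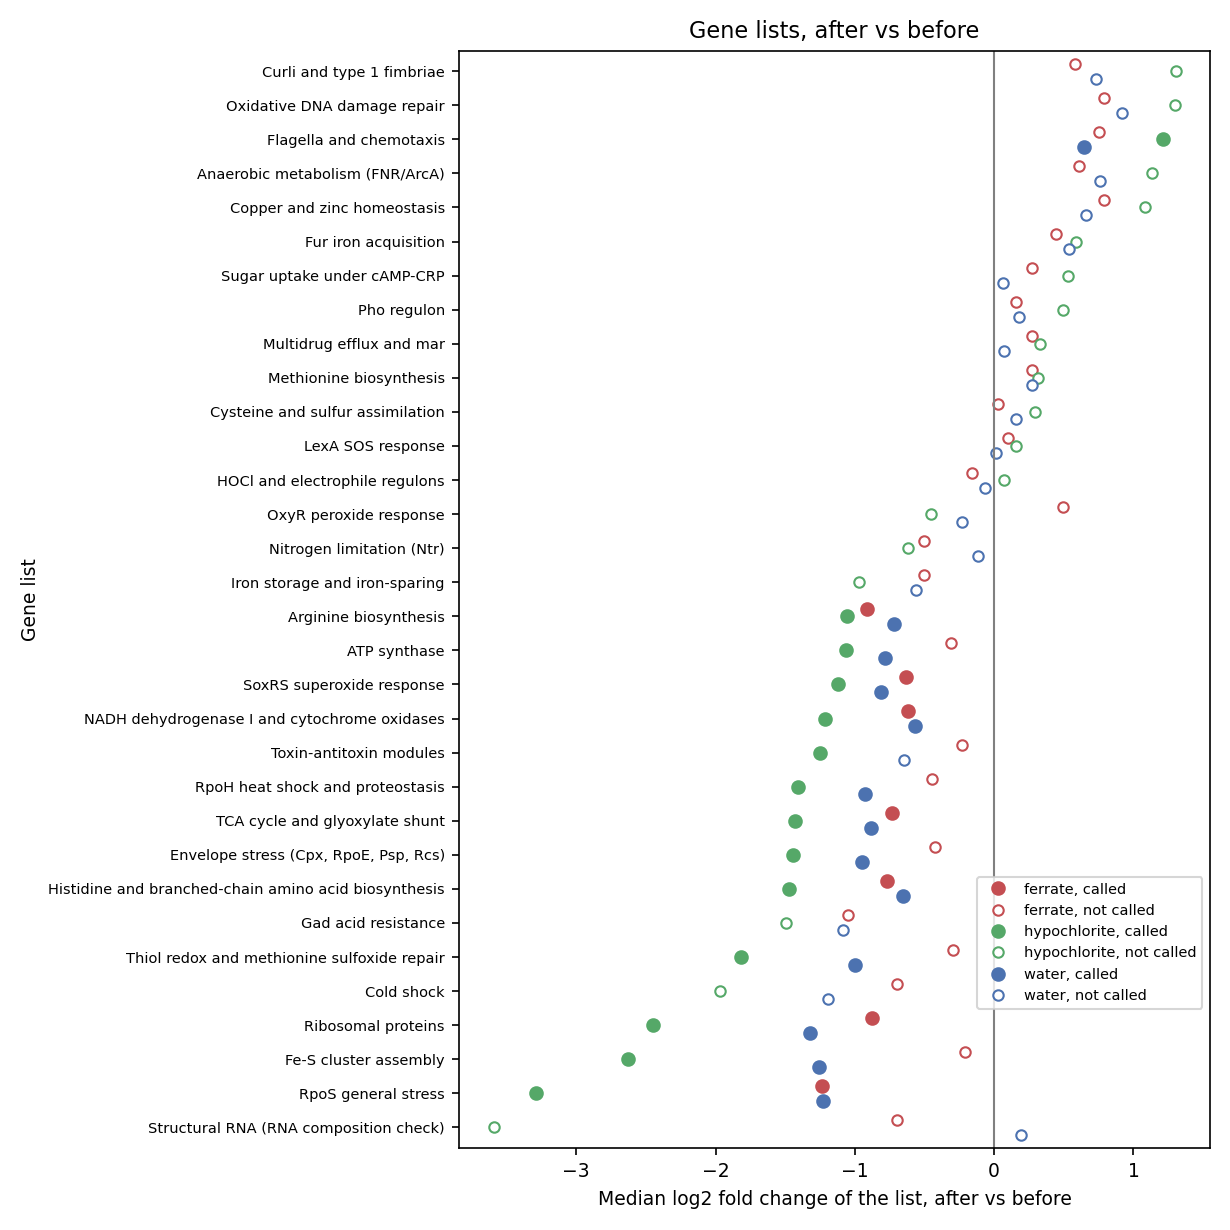
Median log2 change of the members of each of the 32 gene lists in the 3 after against before comparisons, with filled points for lists that passed camera and open points for those that did not. The ribosomal protein list has a median of -0.88 in ferrate, -2.45 in hypochlorite and -1.32 in water.

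Ferrate and water were compared directly after exposure, the comparison that holds the handling of the flasks in common. yjbE, trxC and mntS were the genes most raised in ferrate. yjbE, of an exopolysaccharide operon (b4026, positions 4235906 to 4236148), was higher by 3.66 ± 0.60 (SE, n = 3 flasks, adjusted p = 0.00713), at 128 against 17.4 times the flat level. trxC was higher by 3.47 ± 0.62 (adjusted p = 0.0115), at 85.4 against 13.4 times (1.60, 33.5 and 5.07 in water cultures A, B and C), and mntS, a small protein tied to manganese (b4705, positions 852869 to 852997), by 2.88 ± 0.52 (adjusted p = 0.0115), at 58.8 against 12.9 times (2.70, 29.9 and 6.16). The water means of trxC and mntS are thus carried by culture B. Without the after libraries of cultures A and C of water and hypochlorite the 3 differences were smaller, at 2.67, 2.45 and 2.08 (adjusted p = 0.000792, 1.83e-05 and 0.000394). katG was higher by 1.08 ± 0.18 (adjusted p = 0.00713), which RLE size factors take to 0.93 (adjusted p = 0.0522). The 7 other sentinels lay between -0.14 and 1.00, with adjusted p from 0.52 to 0.999.

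In all, 30 genes were higher in ferrate than in water after exposure and 0 lower, with 505 at an unadjusted p under 0.05. DESeq2 called 295, 68 of them higher, with 22 of the 30 shared. RLE size factors moved the median by -0.15 and gave 15 higher and 1 lower, and a fit of these 6 libraries alone called 0 (196 at an unadjusted p under 0.05). The count was 352 without water after A, only 33 of them higher, and 665 without water after B, 652 of them higher. It was 3 without water after C, 18 without ferrate after A and 15 without ferrate after B, all higher. Without the after libraries of cultures A and C of water and hypochlorite it was 1209, 311 higher and 898 lower, and 23 of the 30 stayed higher, 11 of these not clear of the flat level in the model of dilution. The difference grew for 7 of the 30, among them grxA (2.39) and azoR (1.85). Among the 30, chosen for mention after their values were seen, were grxA (1.99, adjusted p = 0.00671), azoR, a quinone reductase (1.60, 0.00111), yqhD, an aldehyde reductase (0.96, 0.00559), and yebG of the SOS regulon (1.77, 0.00713).

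The change in ferrate was then set against the change in water, which also takes out differences between flasks before exposure. azoR (b1412, positions 1482255 to 1482860) rose more in ferrate by 1.70 ± 0.26 (SE, n = 3 flasks, adjusted p = 0.0351), standing at 2.40 times the flat level before and 2.75 after ferrate and at 2.61 and 1.09 in water. It was the 1 gene of 4385 to pass, with 231 at an unadjusted p under 0.05. The call is lost with culture as a block (1.71, adjusted p = 0.0537) and under RLE size factors (1.59, adjusted p = 0.0805, median shift -0.10). DESeq2 called 24 genes, 11 of them higher, among them katG (0.81 in DESeq2, adjusted p = 0.0321), grxA (2.31 in edgeR, adjusted p = 0.0993) and trxC (3.56, adjusted p = 0.315). Without the after libraries of cultures A and C of water and hypochlorite the count was 687, 76 higher and 611 lower, and azoR (1.98, adjusted p = 0.0016), grxA (2.74, 0.00836) and trxC (2.57, 0.000124) passed as higher. The count was 285 without water after B (278 higher), 5 without water after A (1 higher), 5 without ferrate before B (5 higher), and 0 without any other of the 12 libraries (158 to 231 at an unadjusted p under 0.05).

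In this comparison 5 lists were higher in ferrate, with 0 of their genes passing the test over all genes. The OxyR list had a median of 0.30 (camera adjusted p = 0.000336, and adjusted p = 0.0618 with an estimated correlation), and 3 of its 13 genes were higher adjusted over the list alone, with grxA and trxC leading. Ribosomal proteins (0.37, adjusted p = 0.000336), thiol redox (0.20, 0.00105), RpoH heat shock (0.38, 0.00172) and envelope stress (0.07, 0.0435) were higher too, with adjusted p = 0.927 with an estimated correlation. These 4 had 0, 2, 0 and 1 genes higher adjusted over the list alone. Of the 5 lists 0 kept the call without the after libraries of cultures A and C of water and hypochlorite. OxyR stayed higher in direction (median 0.56, adjusted p = 0.234), and these 4 turned lower (medians -0.16 to -0.53), with ribosomal proteins passing as lower (adjusted p = 0.00401). Members not past the test were rpmF at 2.55, clpB at 1.55, htpX at 1.05, spy at 0.95 and degP at 0.70. Under RLE size factors the envelope stress median was -0.02. With culture as a block Fe-S cluster assembly passed as higher (adjusted p = 0.0427 from 0.127) and curli and fimbriae as lower (0.0427 from 0.0521). Without water after A or ferrate before A 2 lists passed, and without water after B 13.

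Hypochlorite was compared with water in the same ways. After exposure, edgeR called 0 of 4385 genes (899 at an unadjusted p under 0.05), while DESeq2 called 718, 10 of them higher. The sentinels ran from -1.21 for soxS (adjusted p = 0.26) to 0.35 for fecA (0.501), with katG at 0.00 (0.998) and, under DESeq2 and RLE, at -0.047. DESeq2 called cysK (-0.97, adjusted p = 0.0424) and recA (-0.79, 0.0471) lower. The count was 1013 without water after A (11 higher) and 1543 (500 higher) without the after libraries of cultures A and C of water and hypochlorite. For the change in hypochlorite against the change in water edgeR called 0 genes (598 at an unadjusted p under 0.05) and DESeq2 123, 0 of them higher. This count was 616 without water after A (19 higher) and 1443 (480 higher) without the same 4 libraries.

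By lists, 13 passed camera in the change in hypochlorite against water, 12 of them lower, with adjusted p = 0.60 to 0.713 with an estimated correlation. They were led by ribosomal proteins (median -1.11, camera adjusted p = 3.93e-07), RpoS (-1.99, 8.15e-07), structural RNA (-3.43, 1.38e-05), Fe-S cluster assembly (-1.26, 0.000268) and the TCA cycle (-0.68, 0.00123). NADH dehydrogenase and oxidases (0.00393), histidine and branched-chain amino acids (0.008), toxin-antitoxin modules (0.00986), SoxRS (0.0376), and thiol redox, arginine and ATP synthase (0.0451 each) were lower, and flagella higher (0.31, 0.00269). With culture as a block arginine no longer passed (adjusted p = 0.0605). The structural RNA list was set beforehand as a check of RNA composition, in libraries depleted of rRNA. rRNA took 66.2, 4.35 and 33.6% of all counts in water after A, B and C. It took 10.5, 6.57 and 3.19% in hypochlorite after and 4.09 to 36.3% before, so the call of this list is not read as a response. Of the 13 lists 8 stayed without the after libraries of cultures A and C of water and hypochlorite, and structural RNA (adjusted p = 0.74), NADH dehydrogenase (0.10), histidine and branched-chain amino acids (0.22), arginine (0.107) and ATP synthase (0.372) were lost. That fit leaves 1 library after exposure in water and 1 in hypochlorite, so the calls kept in it do not show that the lists hold. Members not past the test in edgeR (adjusted p = 0.361 to 0.393) were elaB at -3.32, yjbJ at -3.35, rrsA, a 16S rRNA gene, at -4.10, rpmE at -2.42, iscS at -2.19, sodA, a superoxide dismutase, at -2.16, and fliI at 1.13. Of these DESeq2 called elaB, yjbJ, rrsA, iscS and sodA (adjusted p = 0.0249 to 0.0476). Adjusted over the list alone, 1 RpoS gene was lower and 0 genes passed in the other 12 lists. Without the after libraries of cultures A and C of water and hypochlorite rrsA was at -1.64. The other members named were then at -3.95 for elaB, -4.03 for yjbJ, -2.65 for rpmE, -2.84 for iscS, -2.94 for sodA and 2.22 for fliI.

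The changes in ferrate and in hypochlorite were compared with each other, the question in the title of the series. The changes went together across genes (Pearson r = 0.887, Spearman rho = 0.913 over 4385 genes, which are not independent replicates). Water went with them as well, at r = 0.881 (rho = 0.902) with ferrate and r = 0.947 (rho = 0.971) with hypochlorite. Of the genes called in both, 1634 were higher in both, 924 lower in both and 17 opposite, where independent calls would give 785.6 and 374.8. Water shared 2010 calls of the same sign with ferrate (2 opposite) and 2399 with hypochlorite (0 opposite).

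**Figure D4:**
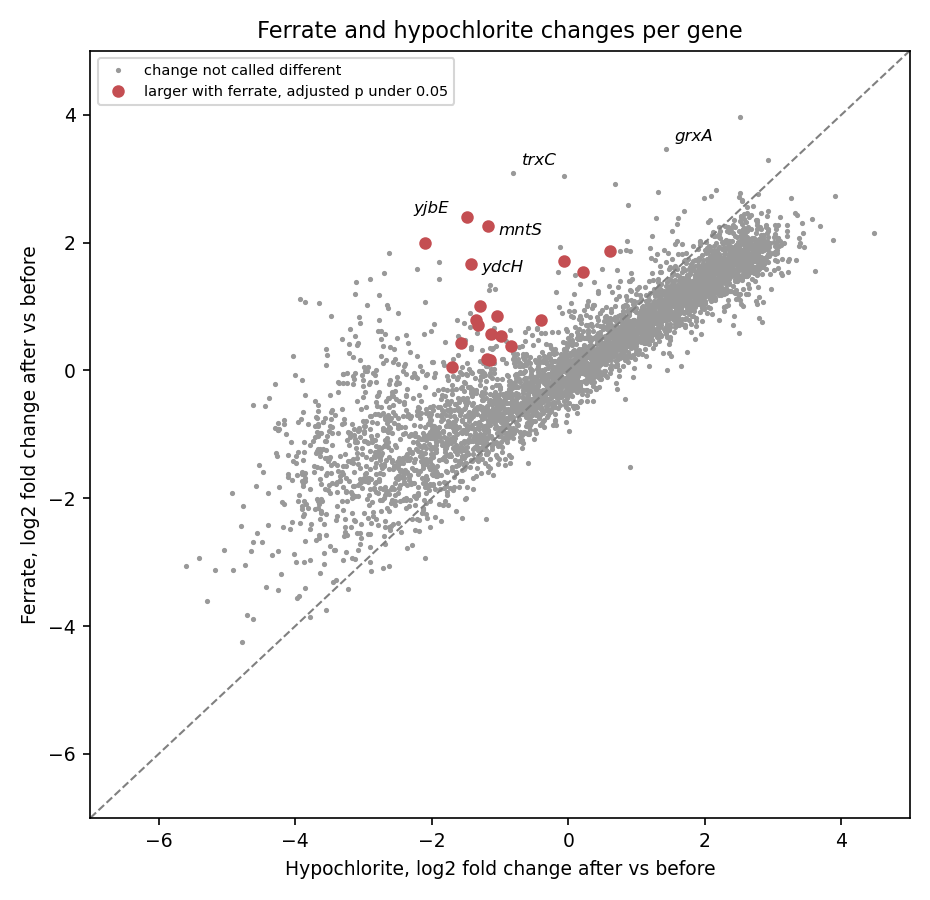
Log2 change in ferrate (vertical) against log2 change in hypochlorite (horizontal), with each point a gene, the dashed line for equal change and larger points for the 19 genes whose changes were called different. The 4385 genes follow a common trend (r = 0.887), and yjbE, mntS and trxC lie above the line.

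The genes by which ferrate exceeded hypochlorite were again yjbE (3.88 ± 0.80, SE, n = 3 flasks, adjusted p = 0.0478) and mntS (3.43 ± 0.71, 0.0478), followed by ydcH (3.08 ± 0.59, 0.0414). With smaller differences came grcA, which replaces a damaged part of pyruvate formate-lyase (1.77 ± 0.30, 0.0321), fruK of fructose breakdown (1.36, 0.0414), yfcZ (1.32, 0.0463), araF of arabinose uptake (1.18, 0.0339) and the antitoxin chpS (1.32, 0.0463). These differences have a limit, since the flat share after exposure was 31.6 to 34.6% in ferrate and 55.6 to 84.7% in hypochlorite. A larger flat share by itself lowers expressed genes, and how much of each difference comes from this was not tested. Leaving out hypochlorite after A and C does not remove the limit, since culture B stands at 55.6%. The doses of the disinfectants differed as well. In all 19 genes passed, each with the higher change in ferrate, with 716 at an unadjusted p under 0.05. DESeq2 called 216, 167 of them higher, with 14 of the 19 shared. trxC (3.89, adjusted p = 0.0573), grxA (2.04, 0.0646) and katG (1.11, 0.0646) did not pass. DESeq2 called trxC and katG (adjusted p = 0.000439 and 0.000212), and a fit of the 12 libraries compared, which called 578 genes (487 higher), had all 3 (0.00366, 0.0117 and 0.0117 for trxC, grxA and katG). With culture as a block the count was 33 and trxC passed (4.10, adjusted p = 0.0371). With flask as a block the count was 0 (646 at an unadjusted p under 0.05), as it was under RLE size factors (761) and with structural RNA left out (675). It was 79 without hypochlorite after B, 0 to 7 without any other of the 12 libraries, and 283 (258 higher) without the after libraries of cultures A and C of water and hypochlorite, with 18 of the 19 shared. Then yjbE was at 2.99, mntS at 2.38 and trxC at 2.91 (adjusted p = 0.000565), and the call of yfcZ was lost (1.04, adjusted p = 0.0722).

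By lists, 13 were higher in the ferrate change than in the hypochlorite change and 2 lower. The unequal flat shares after exposure are a limit for these lists too. OxyR had a median difference of 0.65 (camera adjusted p = 0.00296, and adjusted p = 0.338 with an estimated correlation) and 5 of 13 genes higher adjusted over the list alone. The other 14 lists had adjusted p = 0.535 to 0.636 with an estimated correlation. Ribosomal proteins (1.32, camera adjusted p = 6.36e-13), RpoS (2.30, 1.8e-07), Fe-S cluster assembly (2.00, 9.27e-06), structural RNA (2.81, 2.05e-05), thiol redox (0.66, 3.47e-05) and RpoH heat shock (0.64, 0.000115) were higher. Adjusted over the list alone they had 1, 8, 8, 0, 4 and 0 genes higher. The structural RNA list is again a check of RNA composition and is not read as a response. Envelope stress (0.73, 0.00319), the TCA cycle (0.68, 0.00199), toxin-antitoxin modules (0.87, 0.00199), ATP synthase (0.57, 0.0103), NADH dehydrogenase and oxidases (0.32, 0.0291) and SoxRS (0.48, 0.0349) were higher, and flagella (-0.37, 0.00199) and curli and fimbriae (-0.57, 0.0263) lower. Of the 15 lists 9 stayed without the after libraries of cultures A and C of water and hypochlorite, and envelope stress, toxin-antitoxin modules, ATP synthase, NADH dehydrogenase, SoxRS and curli were lost (adjusted p = 0.0517 to 0.274). That reduced fit leaves 1 hypochlorite library after exposure, so the calls kept in it do not show that the lists hold. Members not past the test in the edgeR fit of all 18 libraries were osmB at 3.95, sodC at 4.09, erpA at 2.40, nfuA at 2.19, clpB at 2.11, soxS at 2.45 and rpmF at 3.78, which passed with culture as a block (4.10, adjusted p = 0.0371). These 7 passed under DESeq2 (adjusted p = 0.00624 to 0.0494) and in the fit of the 12 libraries (0.00222 to 0.0141).

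Before exposure the flasks were compared as a check of their starting point. cysH, which reduces activated sulfate (b2762, positions 2887578 to 2888312), was higher than in the water flasks by 1.40 ± 0.21 in the ferrate flasks (SE, n = 3 flasks, adjusted p = 0.0285) and by 1.38 ± 0.21 in the hypochlorite flasks (adjusted p = 0.0355). It was the 1 gene called in each, with 102 and 172 at an unadjusted p under 0.05, and DESeq2 called 6 and 18. Under RLE size factors neither call stayed (adjusted p = 0.0898 and 0.0796). Without ferrate before A the first call remained, and without any other of the compared libraries each count was 0 (74 to 129 and 100 to 338 at an unadjusted p under 0.05).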

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

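The tests on the flat component, on hypochlorite as the only cause, on swapped labels and on the water libraries in doubt were chosen after the results were seen. The tests on transcript length and on other splits of the samples were not. The length test still rests on the model of dilution, which was chosen after seeing the data.

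A large part of the 4385 genes was called after hypochlorite (3681) and after water (2443). Hypochlorite as the only cause is argued against by the water flasks, since 2 of 3 water libraries after exposure have a flat share above that of every library taken before. The lowest flat share among the 3 hypochlorite libraries after exposure is 55.6%, far above the 9 libraries before. This argues only against a swap that put a water library with a low flat share among them. A swap with water after A or C, at 87.8 and 55.4%, cannot be told apart and stays open. Hypochlorite after A and C grouped with water after A gave 1005 genes, against 0 for the real labels. A flat component stays open as well, such as reads from genomic DNA or from background transcription left after loss of mRNA. Of the genes called higher after hypochlorite 94.7% lie within 2-fold of the flat level. This share was largely fixed beforehand, since genes quiet before set the level and few genes stand clear of it after hypochlorite. These 1698 genes were at a median of 1.62 times the level before and 1.10 after. Whether a flat component accounts for most of these calls is not settled by this share. Changes predicted by the model of dilution went with those observed at Pearson r = 0.942 to 0.958 in the hypochlorite flasks. In water flasks A, B and C r was 0.975, 0.527 and 0.959. The profile before came from the other 2 cultures, but the flat level and scale came from the library predicted, so these values do not settle it either. A loss of mRNA caused by the disinfectant stays open as an untested biological contribution in the hypochlorite flasks.

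After exposure 30 genes were higher in ferrate than in water. A flat component in the ferrate libraries is argued against for 17 of the 30, which stand at least 2-fold above the prediction of the model of dilution and clear of the flat level, and better survival of short transcripts as the whole cause, since 16 of these 17 stay above the prediction with the trend with gene length removed. The water libraries dominated by the flat component are argued against for 12 of the 17, which are still higher in ferrate without them, with a smaller difference in 16 of the 17, such as yjbE (2.67 from 3.66) and trxC (2.45 from 3.47), while 5 lost the call (0.55 to 1.00 from 0.85 to 1.47). For the 13 genes not clear of the flat level this cause cannot be told apart, since 11 stay higher and 6 show a larger difference, but the 1 water library left has a flat share of 9.89%, below the 31.6 to 34.6% of ferrate. A response of the cells to ferrate may be behind the 12 genes, as a hypothesis found and tested on the same data.

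In the ferrate change against the water change 5 gene lists were called higher in camera, and 0 of them pass with an estimated correlation (adjusted p = 0.0618 to 0.927). For 4 of the lists, 0 of the 4 kept a higher direction without the after libraries of cultures A and C of water and hypochlorite. Their medians were -0.25 for thiol redox, -0.16 for RpoH heat shock, -0.36 for envelope stress and -0.53 for ribosomal proteins. The 1 water library left has a flat share of 9.89%, below the 31.6 to 34.6% of ferrate, which by itself lowers expressed genes in ferrate. Water libraries dominated by the flat component thus cannot be told apart as the cause for these 4 lists. For the OxyR list this cause cannot be told apart, since it lost the call (adjusted p = 0.234) but stayed higher, at a median of 0.56 from 0.30. Without water after A alone the OxyR list kept an adjusted p of 0.0127, against 0.488 to 0.684 for the other 4, and without ferrate before A it had 0.00361, against 0.0894 to 0.177. A response of the OxyR list to ferrate stays open.

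The following results differ between exposures by the test of the difference itself, and are given without weighing. For the ferrate change against the water change 1 gene passed, azoR at 1.70, a call lost with culture or flask as a block and under RLE size factors. For the hypochlorite change against the water change 13 gene lists passed, and 0 with an estimated correlation (adjusted p = 0.60 to 0.713). For the ferrate change against the hypochlorite change 19 genes and 15 gene lists passed, and 0 lists with an estimated correlation (adjusted p = 0.338 to 0.636). The calls of the 19 genes were lost with flask as a block, under RLE size factors and with structural RNA left out. The unequal flat shares of ferrate and hypochlorite after exposure are a limit here too. The named genes were yjbE at 3.88, mntS at 3.43, ydcH at 3.08, grcA at 1.77, fruK at 1.36, yfcZ at 1.32, araF at 1.18 and chpS at 1.32.

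Each comparison of 3 against 3 libraries or flasks has 10 splits, so the share of splits with as large a result is never under 0.1 and cannot go under 0.05. The real split gave 2699 genes for ferrate, 3681 for hypochlorite, 30 for ferrate against water after exposure, 1 for the ferrate change against the water change, 19 for the ferrate change against the hypochlorite change, and 1 and 1 before exposure. In each of these 7 the highest other split gave 0, so that 1 of 10 splits gave as many. For water the real split gave 2443 and the highest other, water after A and C with water before B, 1272, so 1 of 10 again. For hypochlorite against water after exposure the real split gave 0 (899 at an unadjusted p under 0.05 in edgeR, 718 by DESeq2) and 10 of 10 splits as many. The highest was 1005, for hypochlorite after A and C with water after A, which points to a structure of the samples. These are the 3 libraries richest in the flat component (80.6, 84.7 and 87.8%). For the hypochlorite change against the water change the real split also gave 0 (598 at an unadjusted p under 0.05 in edgeR, 123 by DESeq2), 10 of 10 splits as many and the highest 567, for the hypochlorite flasks A and C with the water flask A, which again points to a structure of the samples.

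For the gene lists, the real split and the highest other gave 7 and 12 for ferrate (4 of 10 splits gave as many), 14 and 15 for hypochlorite (5 of 10) and 13 and 13 for water (2 of 10). They gave 5 and 12 for the ferrate change against the water change (6 of 10), 13 and 15 for the hypochlorite change against the water change (2 of 10), and 15 and 14 for the ferrate change against the hypochlorite change (1 of 10). Of the 10 splits 4 part all 3 pairs of a culture, the real one included. Among the others of these 4 the highest gene counts were 1272 for water and 0 for the other 9 comparisons, and the highest list counts were 9, 15, 11, 12, 8 and 13 in the order above.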

How the results depend on the processing

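Leaving out the after libraries of cultures A and C of water and hypochlorite, single libraries in the list tests, and the model of dilution were alternatives chosen after seeing the data. The cause of each change below was not tested, unless the alternative holds fewer libraries. Of 1829 alternative values of the 265 named gene results, 1653 kept direction and side of the threshold, 76 lost and 79 gained the call, and 21 turned sign.

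Leaving out 1 library at a time, counts ran from 1879 to 2793 genes for ferrate, 3449 to 3646 for hypochlorite and 1783 to 2668 for calls shared by both, all within 1.5 times. For water they ran from 910 (without water after A) to 3578 (without water after B). Ferrate against water after exposure ran from 3 (without water after C) to 665 (without water after B, 652 of them higher, while 33 of 352 were higher without water after A), and hypochlorite against water from 0 to 1013 (without water after A). The ferrate change against the water change ran from 0 to 285 (without water after B), the hypochlorite change from 0 to 616 (without water after A), and the ferrate change against the hypochlorite change from 0 to 79 (without hypochlorite after B). Before exposure the counts ran from 0 to 1 for ferrate and were 0 throughout for hypochlorite. List counts ran from 7 to 8, 14 to 14, 12 to 15, 2 (without ferrate before A or water after A) to 13 (without water after B), 9 to 15 and 13 to 15 in the order ferrate, hypochlorite, water, ferrate against water change, hypochlorite against water change, ferrate against hypochlorite change.

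DESeq2 called 295 genes for ferrate and 718 for hypochlorite against water after exposure, 68 and 10 of them higher. It called 24, 123 and 216 for the changes of ferrate against water, hypochlorite against water and ferrate against hypochlorite, 11, 0 and 167 of them higher, and 6 and 18 before exposure. RLE size factors gave 16 for ferrate against water after exposure, and edgeR with them 0 for the ferrate change against water, 0 against hypochlorite and 0 and 0 before exposure (270, 761, 101 and 173 at an unadjusted p under 0.05). The stricter filter gave 2 genes for the ferrate change against water. Culture as a block gave 0 (232 at an unadjusted p under 0.05) for the ferrate change against water and 33 against hypochlorite, and flask as a block 0 and 0 (212 and 646). Structural RNA left out gave 0 for the ferrate change against hypochlorite and 0 and 0 before exposure (675, 89 and 169). Only the groups compared gave 0 for water (1781), 0 for ferrate against water after exposure (196), 0 for the ferrate change against water (176), 578 against hypochlorite, and 0 (98) and 5 before exposure.

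Without the after libraries of cultures A and C of water and hypochlorite, the counts were 0 for water (152), 1209 and 1543 for ferrate and hypochlorite against water after exposure, and 687, 1443 and 283 for the 3 comparisons of changes, in a design with 1 library in each reduced group. The model of dilution gave 262 clear genes for ferrate, 46 for hypochlorite and 22 for water, of which 193, 43 and 22 were higher.

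With an estimated correlation 0 lists passed in each of the 6 comparisons tested. fry called 13 lists for ferrate, 25 for hypochlorite, 1 for the ferrate change against water, 0 for the hypochlorite change against water and 1 for the ferrate change against hypochlorite. In the model of dilution 0, 0 and 0 lists passed for ferrate, hypochlorite and water. A list was tested there only with 3 or more genes observed or predicted at 3 or more times the flat level. In hypochlorite and water most lists had fewer, such as 1 of 54 ribosomal protein genes in each. The 0s of hypochlorite and water were thus close to fixed and say nothing about most lists. Culture as a block changed 4 list calls, each given with its result apart from structural RNA after hypochlorite, lower at adjusted p = 0.0275 from 0.101.

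Blocked values that change a call stand with their results, fldB (1.24, adjusted p = 0.0434) and atpC (1.47, 0.0378) in the ferrate against hypochlorite change also passed with culture as a block, and no other call of a named gene changed with it. Values that turned sign were small. fecA after ferrate was -0.20 under DESeq2 and RLE, -0.085 with structural RNA left out and -0.091 with only the groups compared. ibpA after hypochlorite was -0.011 under DESeq2 and -0.013 under RLE. In water ibpA was -0.034, -0.028 and -0.0057 under DESeq2, RLE and with structural RNA left out, and fecA -0.026, -0.026 and -0.011. katG in hypochlorite against water after exposure was -0.047 under DESeq2 and RLE and -0.029 with structural RNA left out, and rclA in the hypochlorite change against water -0.051 under RLE. Before exposure, in ferrate against water, ahpC was -0.00356 under DESeq2 and RLE, -0.00465 with structural RNA left out and -5.39e-05 with only the groups compared, and ibpA was 0.00424 with culture as a block. A transcript below the flat level cannot be told apart from the flat component.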

Other observations

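The tests in this part were chosen after the results were seen, except the comparison of ferrate departures with hypochlorite culture B. That comparison still rests on the model of dilution and the flat share, both chosen after seeing the data, so it is not independent of them. The genes in the next paragraphs were chosen after their values were seen.

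The model of dilution gives changes of single genes beyond a flat component and a common loss, relative to the median expressed gene. In ferrate 193 of 774 genes observed or predicted at 3 or more times the flat level were clearly higher and 69 clearly lower. Higher here means above a prediction scaled by 0.541, 0.275 and 0.410 in cultures A, B and C. A gene counted as higher may thus have fallen less than the median expressed gene, without a rise. Departures went with shorter genes (Spearman rho = -0.271 with length, median length 384 bp for the clearly higher genes against 699 bp for the others of the 774), and 165 of the 193 stayed clearly higher with the trend with length removed. Beside trxC (4.42), yjbE (3.99) and mntS (3.63), the higher genes held bhsA, of the outer membrane (3.04), and the ribosome hibernation factors raiA (3.07) and rmf (2.12). The DNA-binding protein of starved cells, dps, stood at 2.17. The toxin genes dinQ (2.74) and tisB (2.41) and the periplasmic Cpx targets cpxP (2.22) and spy (1.40) were higher, as were the chaperones clpB (1.62) and dnaK (1.43) and the redox genes grxA (2.01), grxB (1.37) and trxA (1.34). Of 12 Fe-S cluster assembly genes among the 774, 7 were higher, sufA (2.36), sufB (1.58), sufC, sufD, sufS, sufE and erpA (1.28). These make and carry Fe-S clusters, the suf genes under stress and iron limitation. The exact hypergeometric test gives p = 0.0134, and p = 0.254 adjusted over the lists, so the list did not pass. In the edgeR test of ferrate after against before, more genes of this list were lower than higher.

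Clearly lower in ferrate by the same model, predicted at 3 or more times the flat level in each library, were asnA (-2.60), aceA (-2.29), fabG (-2.21), cspC (-1.97), rho (-1.92), hisI (-1.80) and aceB (-1.48). In hypochlorite 43 genes were clearly higher and 3 lower, ycgZ, ariR and ymgC, and in water 22 higher and 0 lower, where simulated genes raised 4-fold were recovered in 0 of 53 cases.

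A hypothesis is that both disinfectants shared part of their response. It was tested on hypochlorite culture B, the library of that group with the lowest flat share. Across 456 genes, which are not independent replicates, its departures from the prediction had Pearson r = 0.680 with those in ferrate (Spearman rho 0.661). Water culture C, with a like flat share (55.4 against 55.6%), had r = 0.283 over 475 genes, and on the 420 genes measured in both libraries r was 0.285 against 0.681. Hypochlorite A and C, with fewer genes clear of the flat level, had r = 0.382 and 0.326 over 132 and 81 genes, near water A (0.298 over 77 genes). Of 135 genes clearly higher in ferrate and measured in hypochlorite B, 52 were over 2-fold above its prediction (median 0.84), against 22 of 128 in water C (median 0.17), 2 of 192 in water B (median 0.041, r = -0.0672) and, in a library with few such genes, 21 of 40 in water A (median 1.11). Of 45 clearly lower genes 22 were over 2-fold below it (median -0.99), against 3 of 51 in water C (median 0.057), 2 of 69 in water B and 0 of 10 in water A. All 22 genes clearly higher in water are among the 43 of hypochlorite, and the 193 of ferrate share 22 with hypochlorite and 16 with water, but with 0 of 53 raised genes recovered in simulated water libraries these overlaps do not decide what is particular to the disinfectants. A response in common may be behind the part of the correlation beyond that of water C, with 1 hypochlorite library carrying the test, and it stays open.

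In the 3 libraries richest in the flat component 111 genes had under 1% of the counts that the flat level gives, and 70 of them lie in 4 runs of neighbours. The runs span insX to argF (9 genes, positions 280114 to 290305 on ASM584v2), ydfK to intQ (38 genes, 1633072 to 1652708), rfbD to gmd (14 genes, 2111077 to 2128314) and intZ to yffS (9 genes, 2558858 to 2565332). The hypothesis that these loci are absent from the cultured strain was tested in the 15 libraries not used to find them, where the 70 genes had 28 counts, 0.0105% of the 266462 that the flat level gives. Repeat reads left out by the counting could not be told apart, since 22 of 22 rRNA genes, which are repeats, have counts, while 28 of the 111 are insertion sequence genes, repeats too. Of these 28, 2 lie in the runs. The cultured K-12 strain may lack these loci relative to the reference, which could be checked against its genome.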
